A study of Mus musculus with 4 samples.

How the data were processed

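Gene expression was measured on 4 single-colour Agilent mouse arrays. In 2 of them the RNA came from islet-like clusters that had been formed from cultured pancreatic cells resembling mesenchymal stromal cells, and in the other 2 it came from islets of Langerhans. Per the labels, 500 ng of total RNA per sample was copied from an oligo-dT primer, amplified by in vitro transcription with Cy3 and hybridised, so the probes report polyadenylated RNA. Group and replicate number were taken from the sample titles. The labels describe pools of 2 to 4 mice but do not say whether the samples of a group came from separate pools, so the p-values measure only the spread between these arrays, which may be technical.

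The deposited scanner files hold spot intensity on a linear scale. Per the file headers they were made with Agilent Feature Extraction 11.5.1.1, which the submitters' processing notes also name, and probe positions are on the mm9 mouse assembly. Per the file headers the processed signal is background-subtracted, with a surrogate for spots not above background, and is then detrended by multiplication. The detrending factors ranged most widely on islet replicate 1 (0.895 to 1.25), and the factor was 1 throughout on islet-like cluster replicate 1, which the software left undetrended. The intensity of the mean pixel, the local background and the background-subtracted spot were also read from the deposited files. The software's flags for spots well above background, saturated or non-uniform were used as given (codes that carry no unit). The authors' value table holds log2 values: each of its columns correlated with the scanner values of its own array at r = 0.99997 or higher and differed from them by about the 75th percentile of the array, so its scale and direction are those of log2 signal with no centring per gene. Its column medians were -3.61 and -3.70 for the clusters and -3.50 and -3.37 for the islets. It served as an alternative only.

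The values analysed were log2 of the processed signal minus the 75th percentile of each array over its non-control probes. Control spots and spots flagged as non-uniform were left out, and the spots of a probe were averaged. Of 55681 non-control probes, 490 had no value on at least 1 array after this and were dropped, mostly on islet-like cluster replicate 1, where 510 spots were flagged as non-uniform against 2, 26 and 4 on the other arrays. A probe was kept when it was well above background on both arrays of at least 1 group, which left 34974 probes. Each gene name of the files was represented by its probe with the highest mean over all 4 arrays, which gave 24596 genes. Of 6998 genes with several probes, 442 (6.32%) had probes called in opposite directions. Accessions of 27509 probes matched the reference gene table (assembly GRCm38.p6, used for names only), which gave 2017 of them a symbol other than the one in the files. The files' names are used here, and a later symbol is given where a named gene has one.

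Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided, no covariates), as islet-like clusters minus islets, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The 4 arrays leave 2 residual degrees of freedom, and the fit added a prior for a total of 9.06. Means are given with the SD over the 2 arrays of a group, and fold changes with the SE of the fit on the log2 scale. A gene none of whose probes was well above background on either array of one group has only a bound there. Its fold is then written as "at least", from the mean of the bright group against the mean, in the dim group, of the higher of that array's lowest signal among well-detected probes and the probe's own signal. The number of arrays limits the precision of every value.

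The 27 gene lists, the tests and the alternatives were fixed before the data were examined. Lists were tested with limma's camera (inter-gene correlation preset at 0.01, 2-sided, adjusted over the 27 lists), and again with a correlation estimated from the residuals and with fry. Of 33 acinar genes 31 were on the array. The 10 erythroid genes gave 9 names there, since Hbb-b1 and Hbb-bt share a name on the array. The pancreatic progenitor list shares 11 of its 14 tested genes with the acinar, duct or islet transcription factor lists. The genes named were fixed by a rule: the 5 highest and 5 lowest fold changes among called genes well above background and unsaturated on all 4 arrays, the 4 genes per direction with the largest bound, up to 3 called members of each list in each direction with the largest changes, and 18 genes always given (hormones, beta cell factors, and acinar, duct, stromal and reference genes). This took 151 genes, of which the text gives the leading ones of each list. No spot was saturated.

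The alternatives were normexp background correction, other scalings, other filters on dim probes, keeping non-uniform spots, averaging a gene's probes, a variance trend with robust fitting, a floor for dim signals, a replicate block, the authors' value table and leaving out each array in turn. The signal before the multiplicative detrend was added after the data were seen. All 4 arrays lie on 1 slide and were read in 1 scan, so no slide or scan effect can be fitted, and each array takes a position of its own on the slide. Probes that the software spots repeatedly allowed a check for arrays deposited more than once: over 250 probes with at least 10 spots the cluster arrays differed with a chi-square of 1327 on 249 degrees of freedom, and over 279 such probes the islet arrays differed with 30134 on 278. The median absolute log2 difference was 0.049 against a spot SE of 0.037 in clusters, and 0.166 against 0.045 in islets. Both pairs therefore differed by more than spot noise and were kept as 2 arrays each. This excludes only an array deposited more than once. It cannot tell separate samples from repeated hybridisations of the same RNA, and the cluster arrays lay closest to spot noise.

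The fit was tested on simulated data with the means and spread of the 24596 genes. With 200 genes changed, 50 of 50 were recovered at an absolute log2 fold change of 4, 41 of 50 at 2, 1 of 50 at 1 and 0 of 50 at 0.5, and 3 of 95 calls were false. In the data 54.8% of the genes tested passed, and with so many calls the adjustment is less strict. These rates therefore hold for the simulated setting, with few genes changed and equal spread in both groups, and do not carry over to the data. With no gene changed, 0 genes and 0 lists passed the threshold. The simulated genes were drawn independently of each other, with variances from the prior of the fit itself. This result therefore does not test how the list tests behave when the genes of a list vary together. Probes of close paralogs (Ins1 and Ins2, the trypsins, the Reg genes, the amylases and the Klk1b kallikreins) may bind each other's RNA, so values within such families are uncertain. The files place the probes used for Gapdh and Pgk1 on chromosomes X and 3, which are not those of these genes. Exon and untranslated region positions of the probes were not used here.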

Results

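The arrays compared islet-like clusters with native islets of Swiss albino mice aged 10 to 12 weeks, all labelled male. Per the labels the clusters were collected after 10 days of induction in serum-free medium on low-adherence dishes. Taurine was added on day 3 at 0.3 mM, and on day 7 the clusters received 100 mM nicotinamide, 3 mM taurine and the incretin peptide GLP-1. The islets came from the same type of collagenase digest. Their titles give 48 h in culture, while their descriptions call them freshly isolated, and which of these holds is not settled by the labels. There were 2 arrays per group and no undifferentiated starting cells among them, so the comparison asks how far the clusters resemble islets and not what induction changed.

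Of 59305 non-control spots, 59.7% and 62.3% were well above background on the cluster arrays and 63.6% and 61.2% on the islet arrays. Across the genes tested, Pearson's r was 0.985 between the 2 cluster arrays, 0.989 between the 2 islet arrays and 0.796 to 0.810 between arrays of different groups (genes are not independent replicates). Of the 10 spike-in control probes added during labelling, 6 were brighter on both islet arrays than on either cluster array by over 1.5 times before scaling, 2 of these with a cluster signal mostly not above background.

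Genes higher in clusters included all 26 matrix genes measured, 17 of 24 mesenchymal stromal markers and 13 of 18 inflammatory mediators, and genes lower in clusters included all 31 acinar and all 20 epithelial junction genes. With an estimated correlation no list test passed (adjusted p = 0.371 for matrix, 0.760 for stromal, 0.812 for inflammatory, 0.378 for acinar and 0.282 for epithelial junction genes). The most strongly higher genes well above background on all arrays were Saa3, an acute-phase serum amyloid protein, at 9.75 ± 0.14 in clusters against -2.28 ± 1.39 in islets (log2, mean ± SD, n = 2), then Ereg, the growth factor epiregulin, with a log2 fold change of 10.39 ± 0.35 (SE), Pi16 (9.87), Heph (8.83) and Pappa (8.81). Fibin, Grem1 (the bone morphogenetic protein antagonist gremlin 1), Saa2 and H60a were not well above background in islets and were higher in clusters by at least 14575-fold, 2937-fold, 1656-fold and 734-fold. In the other direction Cpb1 (-13.10), Amy1 (-12.61), Spink3 (now Spink1, -12.47) and Sycn (-12.41), all pancreatic acinar genes, and Clu (-11.58) were lowest among genes well above background on all arrays. Try5, Pnliprp1, Reg1 and Dmbt1 were not well above background in clusters and were lower there by at least 30197-fold.

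In the limma fit 13490 of 24596 genes (54.8%) passed the threshold, 6545 higher and 6945 lower in clusters, and 9915 of them differed at least 2-fold (4985 higher, 4930 lower). The median log2 fold change of all genes was -0.10. Scaling to the array median moved it by 0.20 and scaling over probes detected on all arrays by -0.19, and fold changes are relative to these centres. With normexp background correction the fold changes of 53 of the 147 called genes taken by the naming rule were smaller by over 1.5 times on the log2 scale, which can take them below the bounds given here. Counted on the fold itself, normexp moved 88 of the 147 by over 1.5 times and the floor for dim signals moved 34. Leaving out islet replicate 1 or 2 moved 30 or 28. Hhex, Krt19, Aif1, Tnf, Car9 and Pdk1 were well above background on 1 of the 2 cluster arrays, and Cdh11, Il1a, Actg2, Tubb3 and Neurod1 on 1 of the 2 islet arrays, so their exact differences rest partly on dim values. Without islet replicate 1 the count was 8588 (4185 higher, 4403 lower), and without islet replicate 2 it was 7936 (3939 higher, 3997 lower).

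**Figure D1:**
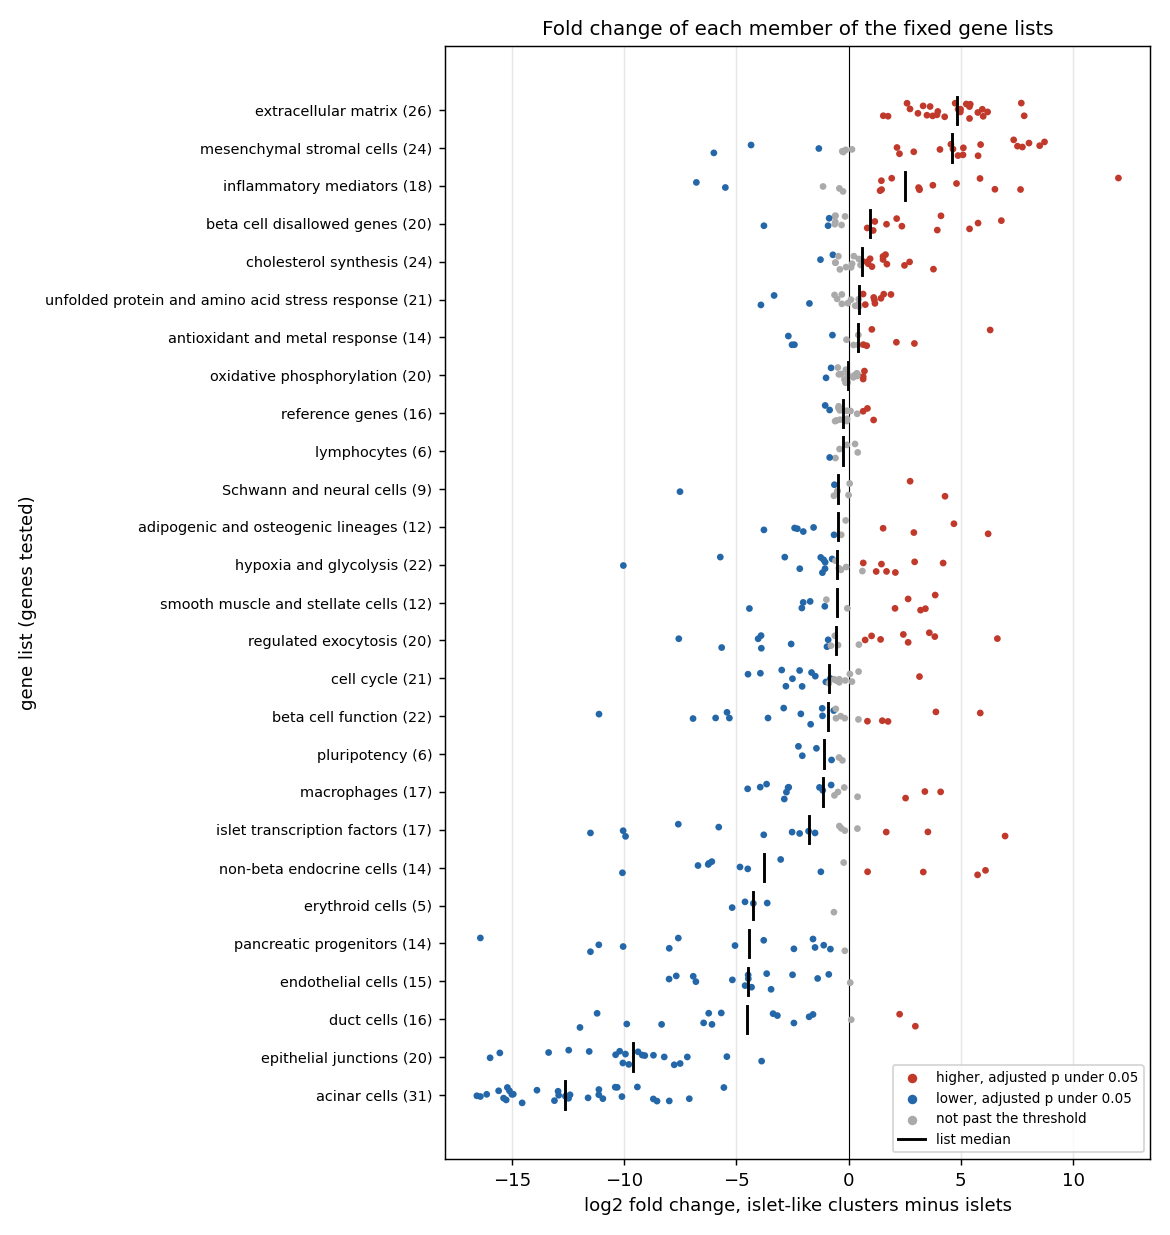
Log2 fold change (islet-like clusters minus islets, x axis) of each tested member of the 27 fixed gene lists (y axis, genes tested in brackets). Red and blue points passed the threshold, grey points did not, and black bars are list medians, which run from -12.61 for acinar cells to 4.82 for extracellular matrix.

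All 31 acinar genes measured were lower in clusters, with a median log2 fold change of -12.61 (-12.41 with the 16 genes that have only a bound held at it). Cpa1, the digestive carboxypeptidase A1, lay at 9.65 ± 0.25 in islets and was not well above background in clusters (at least 29736-fold lower, adjusted p = 1.3e-09, probe on mm9 chromosome 6 from 30595240 to 30595299). All 31 were well above background on both islet arrays and 12 on both cluster arrays. All 20 epithelial junction genes were lower too (median -9.58), led by the keratins Krt18 (at least 28625-fold) and Krt8 (at least 23682-fold) and the adhesion protein E-cadherin, Cdh1 (at least 3944-fold). Of 16 duct genes 13 were lower, 2 higher and 1 did not pass. Krt19, a ductal keratin, differed by -11.96 ± 0.34, and Tff2 and Wfdc2 were lower by at least 670-fold and 266-fold (Wfdc2 differed by -6.49 without islet replicate 1 and -6.46 without islet replicate 2), whereas the secreted phosphoprotein Spp1 (2.98) and the RNA-binding protein Bicc1 (2.28, 1.31 with non-uniform spots kept) were higher. Of 14 pancreatic progenitor genes 13 were lower and Nkx6-1 did not pass, with Cpa1, Foxa2 (at least 1447-fold) and Ptf1a (at least 982-fold) in the lead. Camera called these 4 lists lower, with adjusted p = 3.18e-24 for acinar, 3.18e-16 for epithelial junction, 3.84e-05 for duct and 2.98e-07 for progenitor genes. With an estimated correlation none passed (adjusted p = 0.378 for acinar genes and 0.282 for each of the other lists). Counts adjusted over the list alone were identical for all 4. With normexp the median was -2.86 for duct and -2.55 for progenitor genes, and with probes well above background on all arrays it was -1.30 for the latter.

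Hormone genes were lower in clusters, although both insulin genes stayed well above background there. Ins1 (mm9 chromosome 19, 52339385 to 52339444) lay at -3.46 ± 0.16 in clusters and 3.46 ± 1.85 in islets, a 122-fold difference (log2 -6.93 ± 0.66 SE, limma adjusted p = 1.85e-05). Ins2 (chromosome 7, 149864566 to 149864625) lay at -1.26 ± 0.62 and 4.15 ± 1.84, a 42.6-fold difference (adjusted p = 0.000128). Glucagon (Gcg), amylin (Iapp) and pancreatic polypeptide (Ppy) were not well above background in clusters and were lower by at least 440-fold, 645-fold and 9.61-fold, and somatostatin (Sst) was 22.5-fold lower. These 6 genes differed between the islet arrays by 0.78 to 3.07, being higher in replicate 1. From islet replicate 1 or 2 alone, Ins1 was 301-fold or 49.1-fold and Ins2 105-fold or 17.3-fold lower, and the bounds were 887-fold or 218-fold for Gcg, 1871-fold or 222-fold for Iapp and 17.5-fold or 5.27-fold for Ppy. With normexp the log2 fold changes were -5.37 (Ins1), -4.87 (Ins2), -6.03 (Gcg), -6.58 (Iapp), -1.34 (Ppy) and -2.77 (Sst). With a variance trend and robust fitting the adjusted p was 0.0566 for Ins1 and 0.0917 for Ins2.

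**Figure D2:**
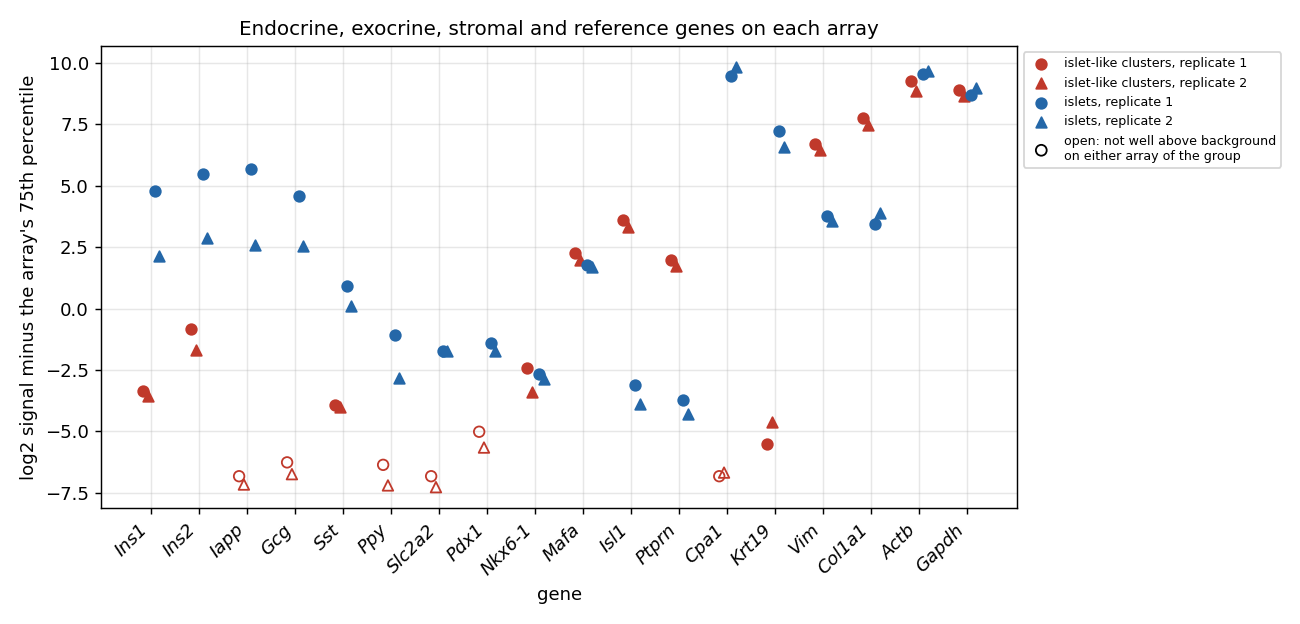
Log2 signal minus the 75th percentile of the array (y axis) for 18 genes (x axis) on each of the 4 arrays. Filled symbols are groups with at least 1 array well above background and open symbols groups with none. Ins1 and Ins2 in clusters lie at -3.46 and -1.26 on average, and Isl1 and Ptprn are higher in clusters than in islets.

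Of 22 beta cell function genes tested 12 were lower, 5 higher and 5 did not pass (13 lower and 5 higher adjusted over the list alone), with a median of -0.91. Besides Iapp and Ins1, Tmem27 (now Cltrn), a beta cell membrane protein, was lower by at least 32.4-fold, and the glucose transporter Slc2a2 by at least 11.1-fold. Tmem27 lay at 0.80 on islet replicate 1 and -1.18 on replicate 2, so its bound depends on the islet array, and its other probe gave -4.54. Ptprn, a dense-core granule protein, was higher in clusters (5.87 ± 0.27), as were Nnat (at least 12.5-fold) and the prohormone-processing carboxypeptidase Cpe (1.76 ± 0.36), which lost its call without cluster replicate 1, cluster replicate 2 or islet replicate 2 (adjusted p = 0.0669 to 0.0891). Of 14 genes of the non-beta endocrine list 9 were lower, 4 higher and 1 did not pass (median -3.76, -3.14 with bounds). Beside Gcg, Hhex differed by -6.71 and Ttr by at least 21.2-fold, while Irx2 (at least 32.7-fold), neuropeptide Y (Npy, 5.75) and the arginine transporter Slc7a2 (3.33) were higher in clusters. Neither list passed camera (adjusted p = 0.0727 and 0.0669), but both passed with normexp (0.0116 and 0.00604) and with a variance trend (0.00946 and 0.00305). With 1 array left out the medians ran from -1.07 to -0.81 and from -4.04 to -3.01. List tests with 1 islet array take their spread from the 2 cluster arrays alone and are not given for these lists. The non-beta list also passed with a floor (0.0418). With normexp the medians were -0.60 and -1.41, and with probes well above background on all arrays -0.57 and -0.72.

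Of 17 islet transcription factors 10 were lower, 3 higher and 4 did not pass (median -1.78). Foxa2 and Hnf4a (at least 837-fold), which act in many endodermal epithelia, were among the lower genes. Pdx1, the pancreatic homeodomain factor, was lower by at least 11.3-fold and Neurog3 by 2.81-fold (adjusted p = 0.00495), the latter losing its call without islet replicate 2 (-0.96), cluster replicate 1 (-1.38) or cluster replicate 2 (-1.61). Isl1 (6.97 ± 0.30, chromosome 13, 117088774 to 117088833) was higher in clusters. Neurod1 was 3.20-fold higher (adjusted p = 0.0229) and lost its call in 10 alternatives, among them the fits without cluster replicate 2 (0.87) and without islet replicate 2 (1.08). Nkx6-1 (-0.16 ± 0.32, adjusted p = 0.691) and Mafa (0.40 ± 0.23, adjusted p = 0.180) did not pass, although Mafa did with median scaling (0.59, adjusted p = 0.0336). Camera called the list lower (adjusted p = 0.0153), but not with an estimated correlation (adjusted p = 0.878), with scaling over probes detected on all arrays (0.0902) or with the authors' values (0.0567). With probes well above background on all arrays its direction turned (adjusted p = 0.231, median -0.16). The median was -0.58 with normexp and -0.87 with no filter on dim probes. Of 20 genes of regulated exocytosis 8 were higher and 8 lower (9 lower adjusted over the list alone). The granule proteins Chgb (-7.56), Chga (-5.65) and Scg3 (-4.03) were lower, and the calcium sensor Syt7 (at least 46.5-fold), the small GTPase Rab3a (3.84) and Syt13 (3.60) higher, and the list did not pass (camera adjusted p = 0.913). Chgb and Chga were 2.69 and 2.19 higher on islet replicate 1 than on replicate 2, so the sizes of their differences depend on the islet array. With a variance trend and robust fitting Chgb and Chga (both adjusted p = 0.0507), Scg3 (0.158) and Syt13 (0.116) lost their calls. Scg3 also lost its call without either cluster array (0.0798 and 0.0752) and was -2.58 without islet replicate 1, and Syt13 lost its call without cluster replicate 1 (0.0546). The acinar genes named above were at high signal on the same islet arrays against which these endocrine genes are compared.

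Mesenchymal genes were higher in clusters. Of 24 markers of mesenchymal stromal cells 17 were higher, 3 lower and 4 did not pass (median 4.61). The mesenchymal transcription factors Twist1 (at least 261-fold) and Snai2 (8.04 ± 0.23) and cadherin 11, Cdh11 (8.52 ± 0.44), were among them, and the lower genes were Ly6a (Sca-1, -6.00), nestin (Nes, -4.34) and Cspg4 (-1.32, lost without islet replicate 1, adjusted p = 0.0538). Cdh11 fell to 2.27 with probes well above background on all arrays, 5.53 with normexp and 5.39 with the mean of its probes. All 26 extracellular matrix genes were higher (median 4.82), with fibronectin Fn1 at 7.82, the gelatinase Mmp2 at 7.70 and decorin Dcn at 6.20. Vim, the intermediate filament vimentin, differed by 2.91 ± 0.24 and Col1a1, collagen type I alpha 1, by 3.94 ± 0.26. Camera called both lists higher (adjusted p = 2.23e-06 and 1.64e-15), neither with an estimated correlation (adjusted p = 0.760 and 0.371). Of 12 smooth muscle and stellate cell genes 5 were higher (Actg2 3.86, Cnn1 3.42, Myl9 3.21) and 5 lower (Tpm1 -4.42, Synm -2.08, Tagln -2.02), and 6 were lower adjusted over the list alone. Tpm1 was -1.53 without cluster replicate 1 and -2.23 with non-uniform spots kept, and Tagln lost its call without cluster replicate 2 (adjusted p = 0.0585). The camera adjusted p was 0.864, the median -0.52 and the mean 0.24, which differ in sign, the test following the mean. Of 12 genes of the adipogenic and osteogenic lineages 4 were higher, led by the lipase Lpl (6.22) and alkaline phosphatase Alpl (4.70), and 6 lower, led by Cxcl12 (-3.77, -2.25 with the mean of its probes) and Pparg (-2.40), with camera adjusted p = 0.795, a median of -0.49 and a mean of 0.19. Among 9 Schwann and neural genes S100b (4.30) and Tubb3 (2.74) were higher and 2 were lower (1 adjusted over the list alone), with Mbp at -7.51 (-4.74 with the mean of its probes). Tubb3 lost its call without either cluster array (adjusted p = 0.0834 and 0.0696) and was 1.78 without islet replicate 2. The camera adjusted p of the list was 0.791.

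Endothelial genes were mostly lower in clusters, while the blood cell lists were less uniform. Of 15 endothelial genes 14 were lower and 1 did not pass (median -4.46, -3.62 with bounds), including VE-cadherin, Cdh5 (at least 77.2-fold), Robo4 (at least 204-fold) and Sox18 (at least 49.1-fold), with camera adjusted p = 8.91e-08 (adjusted p = 0.282 with an estimated correlation) and a median of -2.51 with normexp. Of 17 macrophage genes 10 were lower, among them Aif1 (-4.49) and Cd68 (-3.93), and 3 higher, Tyrobp (4.10), Lyz1 (3.40) and Lyz2 (at least 3.28-fold). Without cluster replicate 1 Lyz1 (adjusted p = 0.0787) and Lyz2 (0.115) lost their calls, as they did without cluster replicate 2 (0.0681 and 0.106). Lyz1 also lost its call with a variance trend (0.151), and Lyz2 with normexp (0.344) and scaling over probes detected on all arrays (0.0731). Without islet replicate 1 they were 2.22 and 1.47. The list did not pass camera (adjusted p = 0.0970), and its median ran from -1.48 to -0.81 with 1 array left out. The haemoglobin genes Hbb-b2 (at least 10.4-fold), Hbb-b1 (now Hbb-bt, at least 7.06-fold) and Hba-a1 (-4.24 ± 0.67) were lower, 4 of 5 erythroid genes passing and 5 adjusted over the list alone. That list's camera adjusted p of 0.0434 (0.878 with an estimated correlation) rose to 0.142 without cluster replicate 1, 0.0848 without cluster replicate 2 and 0.0593 with the replicate block. The other scalings gave 0.0558 to 0.220, the values of the authors 0.113 and keeping non-uniform spots 0.115, and fry did not call it (0.132). Its median of -4.24 was -1.58 with normexp. Without cluster replicate 2 all 3 named haemoglobin genes lost their calls (adjusted p = 0.0502, 0.0781 and 0.0643), Hbb-b1 also without cluster replicate 1 (0.0689) and Hba-a1 with a variance trend (0.130). Hbb-b1 was -2.99 without islet replicate 2. Macrophage and erythroid genes were higher on islet replicate 2 than on replicate 1, by a median of 1.02 and 2.90 (replicate 1 minus 2: -1.02 and -2.90). Of 6 lymphocyte genes 1 was lower and 5 did not pass (camera adjusted p = 0.798 for the list).

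**Figure D3:**
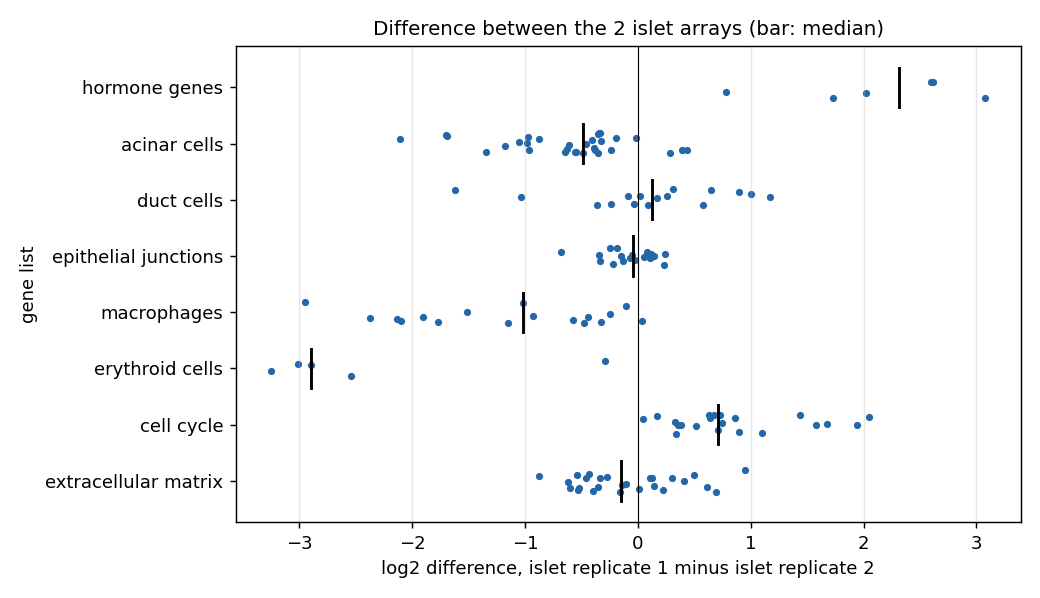
Log2 difference between islet replicate 1 and islet replicate 2 (x axis) for the genes of 8 groups (y axis), 1 point per gene, with black bars at the medians. The 6 hormone genes have a median of 2.31, the acinar genes of -0.48 and the erythroid genes of -2.90.

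Inflammatory mediators were higher in clusters, 13 of 18 genes against 2 lower (3 adjusted over the list alone), with a median of 2.52. Beside Saa3, the prostaglandin synthase Ptgs2 differed by 7.66 ± 0.23 and interleukin 1 alpha, Il1a, by 6.52 ± 0.61, while Icam1 (at least 32.0-fold) and Tnf (-5.49) were lower. The camera adjusted p was 0.00146 (adjusted p = 0.812 with an estimated correlation). Of 21 cell cycle genes 11 were lower, led by the replication licensing factors Mcm3 (-4.48), Mcm5 (-3.93) and Mcm6 (-2.98), and 1, E2f1 (3.16), higher. That list passed camera (adjusted p = 0.0166), but not with an estimated correlation (adjusted p = 0.935) or by fry (0.132). It also did not pass with scaling over probes detected on all arrays (camera adjusted p = 0.0588) or with a variance trend (0.0603). Its median of -0.88 was -0.39 without islet replicate 1 and -1.47 without islet replicate 2, and its genes differed between these arrays by a median of 0.71. Of 20 genes that beta cells normally repress 11 were higher, among them Igfbp4 (6.81), Pdgfra (5.77) and Cd302 (5.39), and 3 lower (7 adjusted over the list alone), among them Cxcl12 and Zfp36l1 (-0.91). Arhgdib, also called lower (-0.86), has probes called in opposite directions, and the mean of its probes was 0.34. The list's camera adjusted p was 0.0635. It passed in 7 alternatives, among them normexp (0.0022), and by fry (0.0225). Some of the 7 had a single islet array, so their spread came from the cluster arrays alone. Zfp36l1 and Arhgdib each lost their call without cluster replicate 2 and without either islet array (adjusted p = 0.056 to 0.313). Of 24 cholesterol synthesis genes 12 were higher, among them Hsd17b7 (3.78) and Idi1 (2.72), and 2 lower (3 adjusted over the list alone), with camera adjusted p = 0.0536, 0.021 to 0.0493 in the 5 alternatives that passed, and 0.0405 by fry.

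The remaining lists did not pass camera. Of 22 hypoxia and glycolysis genes 7 were higher (8 adjusted over the list alone), led by Vegfa (4.22) and the collagen prolyl hydroxylase P4ha1 (2.95), and 10 lower (11 adjusted over the list alone), led by carbonic anhydrase Car9 (-10.03) and Pdk1 (-5.71), with camera adjusted p = 0.732. Pdk1 was -3.44 without cluster replicate 1 and lost its call with a variance trend (adjusted p = 0.187) and with scaling over probes detected on all arrays (0.0520). Of 21 genes of the unfolded protein and amino acid stress response 8 were higher (Pdia4 1.89, and Ddit3 1.57, lost without islet replicate 2, adjusted p = 0.0591) and 3 lower (Atf3 -3.90, Derl3 -3.32, Xbp1 -1.74), with camera adjusted p = 0.515. Of 14 antioxidant and metal response genes 6 were higher, including the quinone reductase Nqo1 (6.31), Sod2 (2.93) and Srxn1 (2.13), and 4 lower, including the metallothioneins Mt1 (-2.68) and Mt2 (-2.52), with camera adjusted p = 0.412. Of 6 pluripotency genes 4 were lower, among them Esrrb (-2.23) and Myc (-2.06), with camera adjusted p = 0.0635, while fry called the list lower (adjusted p = 0.0225). Of 20 oxidative phosphorylation genes 3 were higher and 2 lower (0 and 1 adjusted over the list alone), with camera adjusted p = 0.864 and a median of -0.04, the test pointing higher. Of 16 reference genes 3 were higher and 2 lower (2 and 2 adjusted over the list alone), led by Ywhaz (1.12) and Pgk1 (-1.04), which both lost their calls without either islet array (adjusted p = 0.0666 to 0.185; with the mean of its probes Ywhaz was 0.59 and with quantile normalization Pgk1 was -0.50), with camera adjusted p = 0.798. Gapdh differed by -0.08 ± 0.24 (adjusted p = 0.802), a sign that turned with median scaling (0.12), quantile normalization (0.40), normexp and the fits without cluster replicate 2 (0.03) or islet replicate 2 (0.07). Actb differed by -0.53 ± 0.25 (adjusted p = 0.0971) and passed with scaling over probes detected on all arrays (0.0219), a variance trend (0.00905) and the authors' value table (0.0494).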

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

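These values were looked for after the data were seen. Of 10 spike-in control probes, which the comparisons above do not use, 6 gave on both islet arrays over 1.5 times the signal of either cluster array, although all 4 arrays share 1 slide and 1 scan. The ratio of the islet mean to the cluster mean, before any scaling, was 1.78 for the brightest control probe (E1A_r60_1), whose 2 arrays per group differed by factors of 1.02 in clusters and 1.00 in islets. It was 1.81 for E1A_r60_n11, 1.69 for E1A_r60_n9 and 1.62 for E1A_r60_a97. For E1A_r60_a135 (1.91) 2 and 9 of 35 cluster spots were well above background, and for E1A_r60_3 (8.90) 0 and 1 of 35, against 34 or more of 35 on each islet array, so the sizes of these 2 ratios are not measured. The slope that the scanner software fitted through the spike-ins was 0.929 and 0.930 on the islet arrays and 0 on both cluster arrays. Among the 4 other control probes, E1A_r60_a22 had a ratio of 1.54, below the factor of 1.5 when the dimmer islet array was set against the brighter cluster array (1.47), and E1A_r60_a20 had a ratio of 0.864. The remaining 2 had at most 3 of 35 spots well above background on any array. The 75th percentile of the processed signal was lower on the islet arrays (389 and 289) than on the cluster arrays (415 and 452). Scaling by it would therefore raise each of these ratios and set the 2 islet arrays further apart. Whether the fold changes of genes are shifted by a similar amount was not tested.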

How the results depend on the processing

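All alternatives but the signal before the multiplicative detrend were planned. Over 17 refits of all genes, 8 of the 11 lists past the threshold stayed past it with the same direction (acinar, duct, epithelial junction, mesenchymal, matrix, endothelial, progenitor and inflammatory genes), and 11 of the 16 others stayed unpassed. Of the 147 named genes called, 111 kept their call and direction in every setting that measured them and 124 in every setting with all arrays. Where a call was lost the cause was not tested, except that leaving out an array leaves fewer samples. The lone array of a group is then assumed to vary like the other group's. The counts of lists and genes over all refits include such fits.

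Leaving out 1 array gave 7936 to 10072 genes past the threshold (3939 to 5421 higher, 3997 to 5324 lower), a share of calls higher in clusters of 46.4% to 53.8%, a median log2 fold change of -0.166 to 0.0280 and a within-group r of 0.986 to 0.989. It ended 17 to 21 of the 147 named gene calls and turned none. Median scaling moved the share of higher calls from 48.5% to 58.1% and the median log2 fold change to 0.0946, and scaling over probes detected on all arrays moved them to 40.3% and -0.29. The lowest within-group r was 0.993 with normexp, 0.992 with probes well above background on all arrays and 0.989 with a floor. With an estimated correlation 0 of 27 lists passed, against 11 with the preset value and 12 by fry. An estimate from 2 residual degrees of freedom is itself imprecise.

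With probes well above background on all arrays the median of the islet transcription factor list shrank from -1.78 to -0.16 and its test pointed higher, since the filter removes genes that the clusters lack. Averaging a gene's probes turned Arhgdib to 0.34, because its probes oppose each other. The replicate block gave 11307 genes, 5729 higher and 5578 lower, and ended the calls of 8 named genes and 1 list. The deviations of same-numbered arrays correlated at -0.02, which gives no sign of pairing by number but does not exclude it. A threshold of 0.01 gave 10135 genes and a 2-fold minimum 9915. The undetrended signal gave 13443 genes, 13168 of them shared in direction. The spreads that decided whether these untested values moved were set after the data were seen: the SD over the 4 cluster and islet pairs was 4.42 points for the share, taken there among genes at least 2-fold apart. Slide and scan as a block were not run, since there is 1 of each. Signal over background limits the dim side: 1213 called genes in clusters and 827 in islets have only a bound.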

Other observations

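All tests in this part were chosen after the data were seen. Genes that share a name prefix were grouped into 189 families of 10 or more tested genes, and camera called 9 of them (none with an estimated correlation, adjusted p = 0.992 for each). Kallikreins, serine proteases of which the Klk1b group is a tight cluster of near-identical genes, had 12 of 17 members lower in clusters and 0 higher (median -6.16). Klk1b26 (at least 8120-fold by the probe used, but -3.93 by its other probe) and Klk1b5 (-13.20, well above background on 1 of the 2 cluster arrays) led. Matrix metalloproteinases had 14 of 19 higher and 4 lower (median 3.98). Mmp13 (7.05), Mmp3 (6.36) and Mmp19 (5.25) were higher, and Mmp15 (at least 164-fold) and Mmp7 (-6.53) lower. These directions held under every scaling tried. With probes well above background on all arrays the median of the 9 kallikreins left was -0.54, and with normexp the metalloproteinase median was 2.57.

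Protocadherin beta genes, adjacent cell adhesion genes, had 10 of 15 higher and 1 lower (median 3.21, 1.12 to 3.41 over normexp and the scalings), with Pcdhb17 at 4.37 and Pcdhb20 at 3.87. Histone genes had 28 of 43 higher and 4 lower (median 1.14, 0.69 to 1.34), led by Hist1h4i (4.00, with its 3 probes from 0.88 to 4.00) and Hist1h2bc (now H2bc4, 2.37). Labelling from an oligo-dT primer means that these values cover polyadenylated histone RNA only. Ribosomal protein genes of the large subunit had 16 of 46 lower and 0 higher (median -0.59, -0.78 to -0.12 over the same settings), led by Rpl22l1 (-1.62) and Rpl32 (-1.18). The other families called were claudins (13 of 17 lower), keratins (18 of 33 lower), collagens (21 of 34 higher) and names beginning with Ly (11 of 17 lower). The families' leading genes were chosen by size of change.

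The islet arrays carried acinar transcripts at high signal, and the acinar list gave the largest shift of the 27. One scaling factor per array is argued against as the source, since the acinar median of -12.61 lay far below that of all genes (-0.10). Refitting with other scalings was no test of this, because they moved the centre of all genes by 0.20 or less. The median acinar difference kept a size of at least 10.62 under them and normexp. Between the islet arrays the acinar genes differed by a median of -0.48 (interquartile range 0.63) and the 6 hormone genes by 2.31. Endocrine cells as the source cannot be told apart by this, because the hormone difference is not shown to follow the share of endocrine cells. On both islet arrays the acinar gene Cpa1 lay above Ins1 (mean 3.46) and Ins2 (4.15), although signals of different probes compare only roughly. All 16 duct and all 20 epithelial junction genes tested were also well above background on both islet arrays. Exocrine cells left in the islet samples were not tested, nor was any biological explanation from the design.

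The 6 hormone genes were higher on islet replicate 1 than on replicate 2, by 0.78 (Sst) to 3.07 (Iapp), as were Chgb (2.69), Chga (2.19) and Scg3 (2.90), while the median difference was -2.90 for erythroid, -1.02 for macrophage and 0.71 for cell cycle genes. One scaling factor per array moves every gene alike and is argued against, since the hormone median lay 2.33 above that of all genes (interquartile range 0.47). A smaller share of endocrine cells in replicate 2 may account for it, but 33.3% (8 of 24) of the other endocrine genes lower in clusters by 2 or more on the log2 scale were higher by 1 or more in replicate 1, and Slc2a2 lay at -1.74 and -1.73 on the 2 arrays and Pdx1 differed by 0.32. This explanation cannot be told apart from lower granule and hormone RNA per cell. Several of the 24 genes (such as Foxa2 and Hnf4a) are also made by other pancreatic epithelia. Other members differed little between the islet arrays, such as Abcc8 (0.28), Nkx2-2 (-0.13), Ttr (-0.03) and Pyy (0.34). Insm1 (2.02), Tmem27 (1.98) and Pcsk2 (1.36) were higher in replicate 1, as the hormone genes were, so the 24 genes give no single answer.

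Of 8 probes for 7 Y-linked genes, 3 were well above background on both cluster arrays and none of these on both islet arrays, although all samples are labelled male. Ddx3y and Uty were not well above background on either islet array (at least 84.1-fold and 6.62-fold higher in clusters), and Eif2s3y was so on islet replicate 1 only (-2.75 against -6.26 on replicate 2). The 9 probes of X-linked homologs had a median difference of -0.57 (clusters minus islets, range -0.71 to 0.77), so most were not lower in islets. Eif2s3x (-0.70 and -0.71) and Kdm6a (-0.66) were higher in islets, while 2 Ddx3x probes (0.77 and 0.65) were higher in clusters. This argues against lower expression of the homologs in islets, but does not test a loss confined to Y-linked genes. Islet samples from female animals would fit the loss of Ddx3y and Uty and the 2 Xist probes, which were well above background on both islet arrays. The Eif2s3y signal on islet replicate 1 goes the other way. The Xist probes were also well above background on both cluster arrays, which carried Y-linked transcripts, so their presence does not separate the groups. Both Xist probes were higher in islets, with a median difference of -0.90 (limma adjusted p = 0.00707 and 0.0330 over probes). Pools of both sexes were not tested, so the sex of the animals behind each array cannot be told apart with these probes. Any difference in sex between the groups would be confounded with the comparison of clusters and islets.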
